A study of Oncorhynchus mykiss with 7 samples.

How the data were processed

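RNA from the proximal intestine of rainbow trout was measured on 1-colour Agilent arrays, 1 fish per array, in 2 feeding groups. The control group of 3 fish ate a feed with 300 g soy protein concentrate per kg. The insect group of 4 fish ate a feed in which 400 g of black soldier fly meal per kg took the place of all the soy protein and to which 3 g of guar gum per kg, a binder, had been added. Per the labels' protocols, the trial ran for 69 days, each feed had duplicate tanks of 55 fish, and the fish on the arrays came from the tanks named A. Groups were taken from the sample titles. Because the fish came from the tanks named A and insect meal and guar gum were given together, tank, insect meal and guar gum cannot be separated here, and the p-values measure the spread between fish only. The listed amounts differ in total between the feeds, so other ingredients must have differed too, and these cannot be separated either. Per the labels' protocols, 50 ng of RNA was amplified and labelled with cyanine 3. The labels list dyes other than cyanine 3 for the arrays insect 3 and insect 4, a different one for each. The file headers give 1 channel on all 7 arrays, so all were read as 1-colour arrays. A channel count does not name the dye, so this conflict of the labels was not resolved.

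The deposited files hold 1 array each, as spot intensity values on a linear scale with background-subtracted and processed signals and spot flags, extracted with Agilent Feature Extraction 12.1.1.1 per the submitters' processing notes. The series table holds, per array, values that match the background-subtracted intensity in the deposited array files at all 62976 spots (largest difference 4.91e-08), so it is not normalised between arrays. Its column medians were 5.69, 5.43 and 3.82 for the controls and 3.08, 3.98, 4.05 and 3.05 for the insect arrays. Its scale, centring and direction are therefore known.

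Each array has 61657 non-control spots of 49255 different probes, of which 37753 have 1 spot and 11452 have 2. Control spots and spots with an outlier flag were left out. The log2 of the processed signal was averaged over the spots of a probe. A probe counted as well above background on an array where a share of over 0.5 of its spots carried that flag. At most 49.0% of the probes did so on any array, so each array was scaled by its 75th percentile over the 18015 probes well above background on all 7 arrays. The 23093 probes well above background on at least 3 arrays were tested with limma 3.58.1 (lmFit and eBayes, diet as the only term, R 4.3.3) and adjusted by Benjamini-Hochberg at a threshold of 0.05. The test, its samples, the filter on at least 3 arrays and most alternatives were fixed before the data were examined. The probes over which the percentile is taken and the rule of a share over 0.5 of the spots were settled after first fits had been seen, and the alternatives to both are among the settings tried.

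The array files used here have no column of gene names. Of the 45347 different identifiers they give, 6230 are the probe's own name, and none of the other 39117 matched the 72772 genes of the reference table used here (assembly USDA_OmykA_1.1), so the planned counts of genes and the 30 gene lists, cell type markers included, were not run, and the planned rule for named genes could not be used. In its place, the 2 probes of smallest p in each direction are named by probe identifier. A probe that was well above background on no array of a group is given as a bound. The bright group's mean is set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Some spots brighter than that lowest signal also lacked the flag, so each bound is approximate. The species on whose sequences the probes were designed was not checked, so a dim probe need not mean a low transcript in trout.

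The share of variance between diets was the between-group sum of squares over all tested probes with values on every array, as a percent of the total, with an exact permutation test over the 35 splits of 7 arrays into 3 and 4. The fit was tested on simulated data: 20 sets of 7 arrays with the means and spreads of 23084 real probes, in which 300 probes were changed. It called 6.5% of true 2-fold, 76.5% of 4-fold and 95.6% of 8-fold differences, and 5.25% of all calls were false. The simulated noise was independent between arrays and equally wide in both groups, with no slide difference or spatial bands. The adjusted threshold is also easier to reach with 300 changed probes than with few. These rates therefore need not hold for the real arrays. Alternatives were another background correction (normexp with an offset of 50 on median spot signals, since the planned mean signals are not among the columns used here), quantile or median scaling, other filters, the series table, a variance trend, array weights, an unmoderated test, slide and replicate number as blocks, and leaving out each array. The slides were told apart by the slide and scan fields of the files: slide 1 held control 1 and all 4 insect arrays, and slide 2 held control 2 and control 3. The number of arrays limits the precision of the values.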

Results

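Intestinal RNA of 3 trout on the soy control feed and of 4 trout on the feed with insect meal and guar gum was compared to ask whether replacing soy protein by insect protein altered transcript levels in the proximal gut. Between 44.9% and 49.0% of probes were well above background on the control arrays and between 41.7% and 45.9% on the insect arrays. No non-control spot was saturated. Log2 signals of the tested probes correlated between arrays at 0.917 to 0.948 within the control group (3 pairs), 0.929 to 0.953 within the insect group (6 pairs) and 0.917 to 0.960 between the groups (12 pairs). These correlations are across probes, which are not independent replicates. The closest pair, at 0.960, was control 1 with insect 3.

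The control arrays were measured less evenly than the insect arrays. The SD between the 2 spots of a probe was 0.27, 0.42 and 0.41 log2 units on control 1, control 2 and control 3, and 0.20 on each of the 4 insect arrays. Block medians across the array surface varied with an SD of 0.15, 0.24 and 0.23 log2 units on the controls and of 0.09 to 0.11 on the insect arrays. Control 2 and control 3, the arrays with the widest values, share slide 2.

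**Figure D1:**
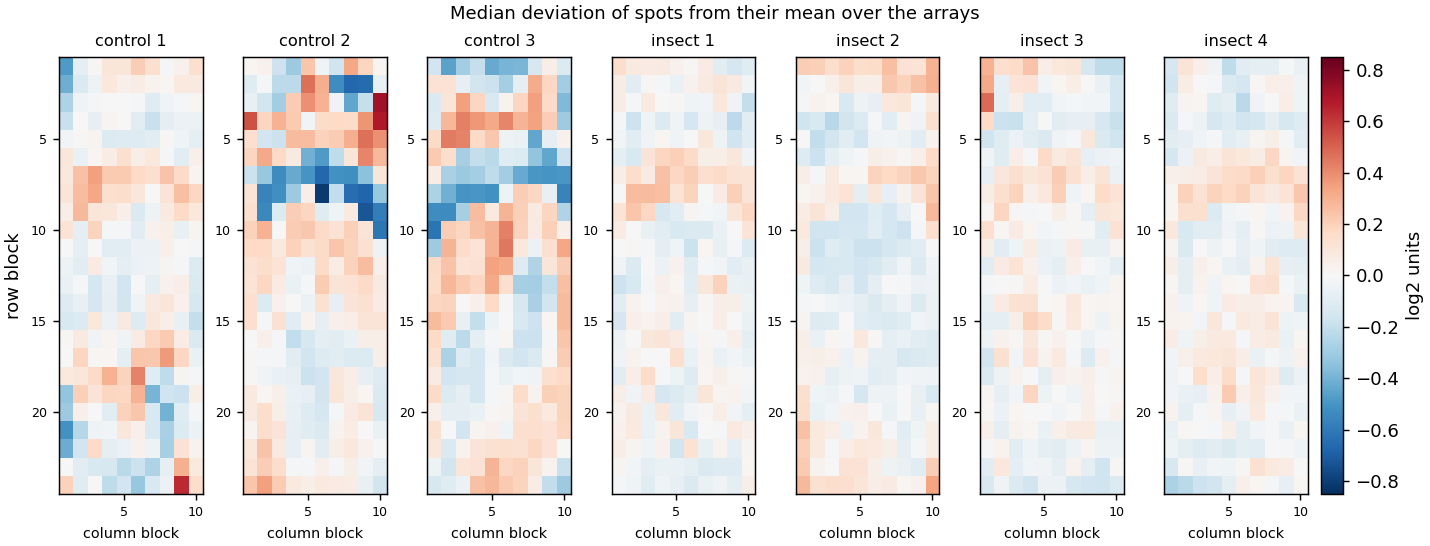
Each panel is 1 array divided into 24 row blocks by 10 column blocks, and the colour gives the median deviation, in log2 units, of the block's spots from their mean over the arrays. Bands are strongest on control 2 and control 3, whose block medians have SDs of 0.24 and 0.23.

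One probe, A_05_P427877, was higher in fish on the insect feed and none was lower, of 23093 probes tested with limma at an adjusted p under 0.05. Its log2 level relative to the array's 75th percentile was -1.92 ± 0.62 (SD, n = 4) with insect feed and -7.02 ± 0.26 (SD, n = 3) in controls. It was well above background on 4 of 4 insect arrays and on 0 of 3 control arrays. Its difference is therefore given as an approximate bound of at least 16.7-fold. The limma adjusted p of 0.00666 belongs to the probe's fitted log2 difference of 5.11. Both of its spots read between 31.5 and 60.6 on the insect arrays and between 1.00 and 5.79 on the control arrays, where 1 spot on control 1 was well above background. The gene behind the probe is not named in the tables used here.

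The probe of the next smallest p among those higher with insect feed, A_05_P407972, had a log2 level of -4.72 ± 0.19 (SD, n = 4) against -6.80 ± 0.47 (SD, n = 3) in controls, where it was not well above background on any array, which bounds the difference at 2.38-fold or more in this scaling. It did not pass the threshold (limma adjusted p = 0.360). Among probes lower with insect feed, A_05_P303952 had a level of -4.59 ± 0.14 (SD, n = 4) against -2.90 ± 0.45 (SD, n = 3), and was well above background on 1 of the 4 insect arrays, so the size of its difference is uncertain. The level of A_05_P247299 was -6.65 ± 0.44 (SD, n = 4) against -4.42 ± 0.65 (SD, n = 3), a bound of at least 1.74-fold lower, since no insect array measured it well above background. Neither passed the threshold (limma adjusted p = 0.420 for both). With normexp background correction the log2 difference of A_05_P407972 was 0.56, that of A_05_P303952 was -0.03, and that of A_05_P247299 turned to 0.21, so these sizes, and the direction of the last, were not kept in that setting, which also starts from median spot signals and adds an offset of 50. The processed signals of these probes lay between 1.25 and 43.6, so an offset of 50 by itself makes such log2 differences smaller. In the main setting, without normexp, the 2 groups did not overlap for each of the 4 probes. These 4 probes were picked by their p, so their lack of overlap is no test. Across all probes tested in the main setting it held for 2237, or 9.69%, where chance gives 5.71% on average. How far this share varies over other splits was not computed, so the excess is no test of diet.

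**Figure D2:**
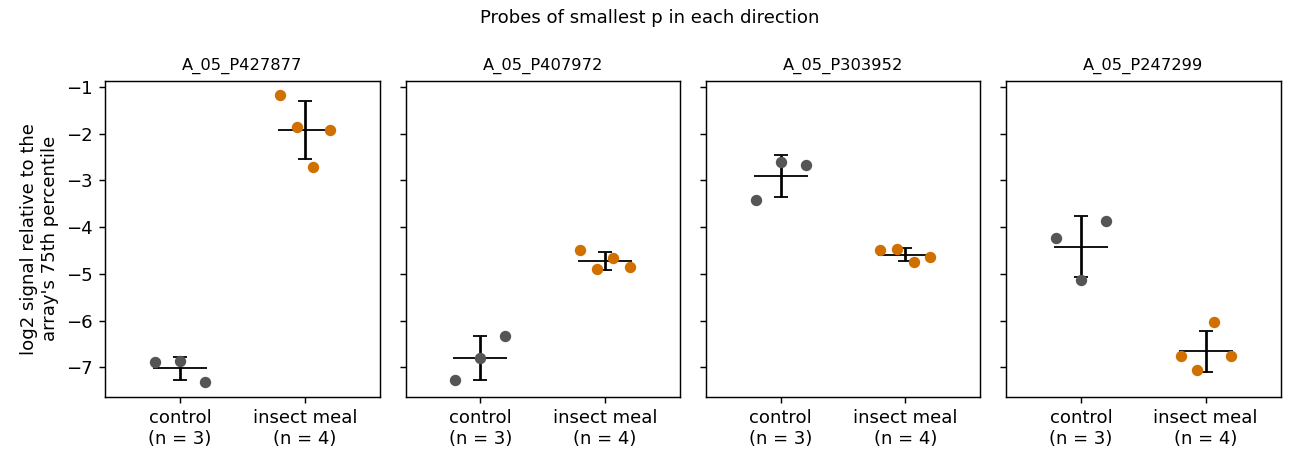
Log2 signal of the 4 named probes relative to the 75th percentile of each array, for 3 control and 4 insect arrays. Points are arrays and bars the mean and SD. Only A_05_P427877, at -1.92 against -7.02, passed the adjusted threshold.

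Slide and diet overlap, since slide 2 held controls only. Control 1 is the only control beside the insect arrays, so a fit with slide as a fixed block and a fit within slide 1 make the same contrast, of 1 control array assumed to vary like the others against 4 insect arrays. The fitted log2 difference of A_05_P427877 was 4.98 in both, with a limma adjusted p of 0.131 with the block and 0.260 within slide 1. With the block 2 other probes passed the threshold, and within slide 1 limma called 0 probes, with 1741 at an unadjusted p under 0.05. The slide term of the blocked fit sets control 1 alone against control 2 and control 3, which cannot tell slide from fish, and had 2554 probes at an unadjusted p under 0.05 and 0 past the threshold with limma. With slide as a random block the probe stayed past the threshold (adjusted p = 0.0156). Its call also ended without insect 2 (log2 difference 5.09, limma adjusted p = 0.0576) or without insect 4 (5.11, adjusted p = 0.0506), where the difference stayed close to the 5.11 of all 7 arrays. With normexp background correction the log2 difference was 1.25 (limma adjusted p = 0.209). Over all settings tried, its adjusted p ran from 0.00279 to 0.633. The number of probes past the threshold was 0 without insect 2 or insect 4, 2 without control 1, control 2, control 3 or insect 1, and 4 without insect 3.

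At an unadjusted p under 0.05 there were 1954 probes, 8.46% of those tested, 1006 higher and 948 lower with insect feed. Of these, 621 differed at least 2-fold, 378 higher and 243 lower. With the 131 of the 1954 probes that were below background on a whole group held at their bound, 551 differed at least 2-fold, 373 higher and 178 lower, and 55 at least 4-fold. The bound thus took out far more lower probes (243 to 178) than higher ones (378 to 373), so part of this upward excess stems from the bound. Of the 1954 probes, none but A_05_P427877 passed the adjusted threshold, the next smallest limma adjusted p being 0.360. The median 95% interval reached 0.72 log2 units on either side of a probe's estimate. With slide as a fixed block, which sets control 1 alone against the insect arrays, 1926 probes had an unadjusted p under 0.05, 1368 higher and 558 lower. On every insect array and no control array 11 probes were well above background, and 206 on every control array and no insect array, and the control arrays had more probes above background on average.

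Diet accounted for 19.6% of the variance between arrays over the tested probes. Of the 35 splits of the arrays into 3 and 4, 11 had as large a share (two-sided exact permutation test, p = 0.314), and the highest share of any other split was 25.5%. Apart from diet, each of these 11 splits put control 1 and insect 3, the closest pair, on the same side. The result of this test therefore depends in part on the likeness of these 2 arrays. The lowest was 10.7%. Within slide 1 the share was 29.3% (exact permutation p = 0.20, the smallest that 1 against 4 arrays allows).

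**Figure D3:**
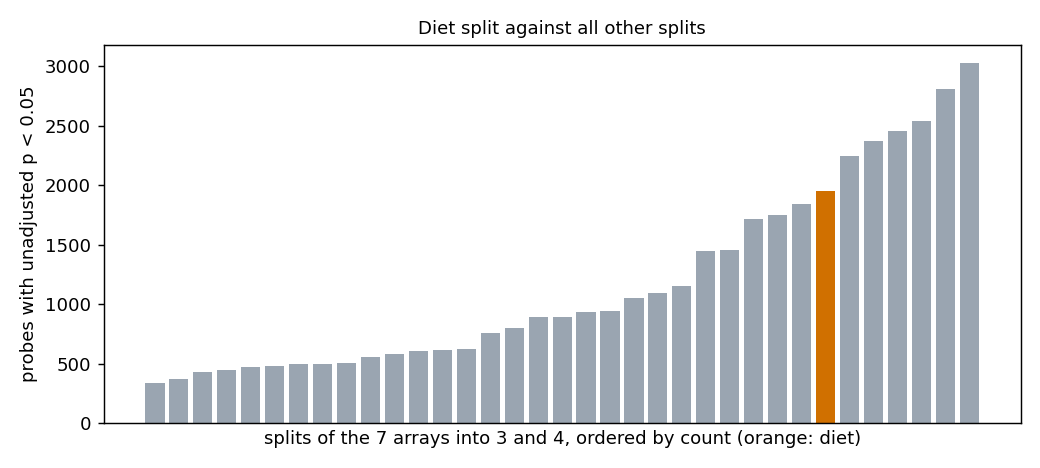
Each bar is 1 of the 35 splits of the 7 arrays into 3 and 4, and its height is the number of probes with an unadjusted p under 0.05. The diet split, in orange, gave 1954 probes, and the highest split gave 3032.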

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

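The tests on splits of the arrays, on the spots of the called probe, on its gap beside other probes and on the spatial trend were chosen after the results were seen, and the counts of probes bright on 1 array alone were defined after insect 3 had been seen to differ.

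Insect 3 stood apart from the other insect arrays in the number of probes over 4-fold brighter than on all other arrays, 264 against 16 to 34, and over 8-fold brighter, 141 against 4 to 12. Among the 4 insect arrays 2 of 19 measures were this far out, both counts of the same kind. Chance gives about 1 in 20, but counts defined after the array was seen to differ are no test of it. Control 2 had 78 and 27 such probes. These counts cover all probes, some of them outside the diet comparison, and require a probe to be well above background only on the bright array. Where the other arrays read near background, the fold is not a measured size. Bright patches on the array are argued against: 1015 neighbouring spots of other probes had a median deviation of 0.010 log2 units on insect 3 (quartiles -0.25 and 0.28). The overall scale or shape of that array's signal is also argued against, since 99.6% of the probes kept the gap after quantile normalisation. Blemishes of single spots stay open for some: among the 44 probes with 2 or more spots, 77.3% had every spot over 2 log2 units above all other arrays, which lies between the bounds set beforehand (50% and 80%). No biological explanation was tested, because the probes could not be matched to gene names.

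The call of A_05_P427877 rests on a wide gap: its dimmest insect spot lay 2.44 log2 units above its brightest control spot. The probe was picked for its difference, so this gap alone tests little, but of 2456 spot pairs on the control arrays from other probes of that brightness 0.244% were further apart, which argues against noise or loss of signal at single spots there. A candidate explanation is an on and off difference between fish that ignores diet. Between neighbouring ranks of the 7 arrays, 52 tested probes had a gap as wide (4.15 log2 units or more), 6 of them between 3 and 4 arrays, and 5 of these followed splits other than diet. Spread evenly over the 35 splits, the 6 would put 0.171 on the diet split, where 1 was seen. That 1 is the probe picked for its difference, and the other 5 only show that such gaps occur without diet, so these counts do not decide. An effect of the feed on this probe stays open.

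Chance could not be excluded for the count of 1 called probe, since 16 of the 35 splits, diet included, called as many and the highest of the others called 4. Nor could it for the 1954 probes at an unadjusted p under 0.05: 7 splits, diet included, gave as many, and the highest other split gave 3032, with control 1, control 2 and insect 3 on one side. Apart from diet, each of these 7 splits put control 1 and insect 3 on the same side.

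Only 1 probe passed the threshold, and the control arrays carried spatial bands. Subtracting the local trend lowered the SD between spots on control 2 from 0.42 to 0.31 and on control 3 from 0.41 to 0.31. Both stayed above the 0.20 to 0.22 of the insect arrays after the same step. It left 1 probe called, which argues against the removed part of the trend as the whole cause. Unevenness that remained on the control arrays was not tested. Whether too few fish for the spread between them could account for the low count cannot be told apart from a small effect of the feed: 76.5% of simulated 4-fold differences were called, between the bounds set beforehand (50% and 80%), but 6.5% of 2-fold ones. The simulation had 300 changed probes and noise that was even across groups and slides, so its rates need not hold for the real arrays.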

How the results depend on the processing

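The settings of spatial correction, slide 1 alone, the percentile over all probes, the spot rule of a share of at least 0.5, and the joint removal of control 1 and insect 3 were chosen after seeing the data. The number of probes past the threshold was 1 under 12 of 24 other settings, and 16 of the 24 called the main probe. It was 0 with probes well above background on all 7 arrays (the called probe is then not tested), 0 with an unmoderated test with unequal variances, 2 with slide as a fixed block, 0 within slide 1, and 0 to 4 when 1 array was left out. With normexp the 1 probe called was another. The count at an unadjusted p under 0.05 was 3257 with normexp, 6676 without a filter (49255 probes tested), 3566 with array weights, 3054 without both control 1 and insect 3, and 1290 to 2939 when 1 array was left out. The percent of such probes that were higher with insect feed was 51.5% in the main setting, 40.7% with median scaling, 82.9% without a filter and 76.8% with normexp, which moved the median difference of all probes to 0.25 log2 units. With normexp A_05_P427877 differed by 1.25 (5.11 in the main setting), A_05_P407972 by 0.56 (2.08), A_05_P303952 by -0.03 (-1.68), and A_05_P247299 turned from -2.24 to 0.21. Causes beyond the offset's shrinkage were not tested. The share of variance ran from 18.98% to 34.4% (exact permutation p from 0.0667 to 0.50). Designs without a control array allow no p under 0.0667, and those without an insect array none under 0.1. No such design could therefore pass 0.05. Diet had the largest share of all splits without control 1 (27.0%, exact permutation p = 0.0667), without insect 3 (26.1%, p = 0.1) and without both (34.4%, p = 0.1). With any other single array left out, the exact permutation p was 0.20 to 0.50. With the replicate block 0 probes passed and 862 had an unadjusted p under 0.05. The deviations of same-numbered arrays correlated at -0.27, 0.16 and -0.32. Deviations cancel out within a group, which ties these values to those of the other pairs. They therefore do not tell whether the numbers mark anything beyond the fish. Gene counts and gene lists were not run, as no probe was matched to a gene name. At most 49.0% of the probes were well above background on an array, so the others are out of reach there.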

Other observations

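Control 1 and insect 3, on different feeds, deviated from their group means in the same direction, with a correlation across tested probes of 0.44, the highest of the 12 pairs between groups. Both lay on slide 1, where the deviations of control 1 correlated with those of insect 1, insect 2 and insect 4 at -0.27, -0.11 and -0.14. Deviations from a group mean cancel out over the group at each probe. A positive correlation with insect 3 thus pushes those with the other insect arrays below zero as a whole, so they do not bear on the slide.

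A probe marked as a control type on the array, ETG10_195139, with 12 spots, had median background-subtracted signals of 783, 39.5 and 63.2 on the control arrays and of 447, 148, 6.37 and 169 on the insect arrays, a 123-fold range, with an SD over its spots of at most 0.30 log2 units. Another, ERCC-00062_278, with 35 spots, read between 105.4 and 245.8 on all 7 arrays. The remaining control-type probes of these 2 kinds read at most 6.44.

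If noise of spots and probes made up the differences between diets, different probes of one accession would differ independently. Across 1759 accessions with at least 2 tested probes, the differences of 2 such probes correlated at 0.252 (Spearman's rho 0.227), between the bounds of 0.1 and 0.3 set beforehand, so the test does not decide how far noise could account for them. For the other 34 splits of the arrays the correlation had a median of 0.278 and a range of 0.176 to 0.496. Accessions are not independent replicates.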
